A study of Mus musculus with 23 samples.

How the data were processed

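Mouse livers of 3 ages (newborn, juvenile, adult) were measured on Visium slides, which carry barcoded capture spots that bind the RNA of a tissue section laid over them. The labels give 6 groups: LV livers, taken 3 days after LV, and untransduced livers of each age. The 23 libraries carry 18 tissue numbers, 3 per group, and the 5 tissue numbers with an A and a B library were read as 1 unit each, with the counts of both libraries added.

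Each library came with a deposited matrix of counts, in which every value is the number of UMIs (unique molecular identifiers, 1 per captured RNA molecule) of a feature in a spot, with no normalization. The authors made it with Space Ranger 1.2.2, a version read from the header of the matrix, against mm10. The 32287 features were 32285 genes with an Ensembl identifier and 2 custom sequences, and 40 repeated symbols were made unique. The deposited spot positions (array row, array column and a flag for tissue) served to find neighbouring spots and are of no measurement unit (other). The deposited images and their scale factors were not used here.

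Total counts per library, the depth, ranged from 6074282 to 48302638 UMIs over 897 to 2281 spots under tissue. Counts were added over all spots of a tissue number. Genes were kept with the filterByExpr function of edgeR by group, which left 14573 genes, and libraries were scaled by TMM. All 18 units were fitted in 1 quasi-likelihood negative binomial model with a mean per group (edgeR 4.0.16 in R 4.3.3, with the data.table package in version 1.17.8), and contrasts between groups were tested two-sided with the quasi-likelihood F-test. The fit had 12 residual and 4.80 prior degrees of freedom and a biological coefficient of variation of 0.166. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference in the LV effect between ages was tested as an interaction over the 3 ages together. CPM are counts relative to the library total scaled by TMM, given as mean ± SD over livers, and log2 changes are given ± SE. This SE is approximate: it was worked back from the test, as the absolute log2 change over the square root of F.

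Position along the axis from the portal tract to the central vein was read from 7 central-side and 7 portal-side genes with a known place in the lobule. In each library, counts were scaled to 10000 per spot, log-transformed and standardised for each score gene detected in at least 5% of spots, and the portal-side mean was subtracted from the central-side mean. Spots were split by this score into a central, a middle and a portal group of equal size. Counts were added per group of spots and tissue number. The central and portal sums were compared in edgeR with the tissue number as a block, over 13379 genes (13365 without the score genes), with a biological coefficient of variation of 0.0325. The score genes are not among the genes called or named. Interactions with age and with LV were tested in the same fit. Zonation strength is the mean log2 ratio (central over portal group, with 1 added to each CPM) of central-side genes held out of the score, minus that of held-out portal-side genes. Spatial autocorrelation is Moran's I, over neighbouring spots, of the standardised central-side minus portal-side held-out genes, averaged over the libraries of a tissue number. Both were compared between ages with two-sided exact permutation tests over tissue numbers (SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, Python 3.11.15), with p adjusted over the 3 pairs of ages. Plots were drawn with Matplotlib 3.10.9.

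The custom sequences were given as CPM of a library or tissue number without TMM. The share of spots with a UMI is given with a 95% exact Clopper-Pearson interval, and the ratio between groups with the 95% interval that follows from the exact binomial split of its UMIs. A count of 0 is given with the level that 3 UMIs would have. These intervals and floors cover counting error only. Host genes were compared between spots with a UMI of the custom sequence and spots without one, paired within library and group when their total UMIs differed by no more than 10%, with counts added per tissue number and a block for the tissue number in edgeR (12559 genes).

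Lists of genes (46, written before the data were examined, as were the tests, the naming rule and the alternatives other than those listed as later choices) covered pathways, liver functions and cell types. A list with at least 5 tested members was tested two-sided with camera (limma 3.58.1), which compares its members with all other genes, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Adjusted p of lists run over the lists of a comparison. Genes were named by rule: up to 10 per direction with the largest log2 change among called genes with a mean of at least 20 CPM and no overlap between the compared livers (between groups of spots, the same sign in every liver). Predicted gene models were counted but not named, some genes that the rule names are not reported here, and where fewer than 5 genes passed, those with the smallest p were given. For a list, up to 3 called members and the most abundant member could be named. Genes named outside this rule are marked as chosen after their values were seen.

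The steps were tested on simulated data drawn with the measured means, depths and spread, in which 100 genes were changed by each factor. In sums over all spots, edgeR recovered 65% of 2-fold changes in the newborn LV comparison, 66% in the juvenile and 64% in the adult one, and 93%, 87% and 91% of 4-fold changes. It called 2, 7 and 6 unchanged genes, and DESeq2 called 13, 17 and 11. Between groups of spots, edgeR recovered 83%, 89% and 87% of 2-fold changes. A list of 20 raised genes had an adjusted p of 2.0e-06 with the estimated correlation, and 0 of 50 random lists were called. The simulated genes were drawn independently of each other, so this says nothing about list tests where genes are correlated, as in measured livers. Whether libraries that share a tissue number repeat each other was checked with the chi-square per degree of freedom between pairs of libraries. It was 3.49 to 12.4 for the 5 pairs that share a number and 8.69 to 148.5 for 28 pairs of the same group that do not. The correlation of deviations from the group mean was 0.606, 0.591 and 0.355 for the pairs of livers 7, 8 and 16. It was -0.131 for liver 13, against -0.390 to -0.332 for other pairs of its group. For liver 4 it was -0.281, within the -0.441 to -0.267 of other pairs of its group, so this measure did not set liver 4 apart.

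Alternatives changed 1 choice at a time, except that the block below was fitted with libraries not added: DESeq2 1.42.0, RLE size factors, no filter on low counts, only spots of at least 1000 UMIs, every spot thinned to 1000 UMIs, libraries not added, the replicate number of the titles as a block, erythroid genes removed, only the groups compared in the fit, untransduced livers only, LV livers in place of untransduced ones, 2 groups of spots in place of 3, a score of the central side only, a pseudocount of 10, a second ring of neighbours, and each tissue number left out in turn. Chosen after the files had been seen were sex as a term, the log2 of UMIs per spot as a term, 1 library per tissue number, the first principal component of the juvenile livers as a term, LV livers only, tests between pairs of ages, and every test of the custom sequences. Sex was read from Xist and Ddx3y. The replicate numbers of the titles were not taken as pairs: of 11 LV and untransduced libraries with the same number, 5 were best correlated with their own number. A correlation above 0.1 was found in 3, all of them among the 4 juvenile pairs (0.533, 0.499 and 0.469), and these join livers on the same side of the first principal component of the juvenile livers. The other splits of the same livers into groups of the same sizes were counted for each comparison, 10 for 3 livers against 3.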

Results

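Spatial gene expression was measured in livers of newborn, juvenile and adult mice on Visium slides, where each capture spot counts the RNA molecules of the tissue above it as UMIs. LV, which the labels do not spell out and which is in common use short for lentiviral vector, had been given 3 days before to 1 arm of each age, and age-matched untransduced livers formed the other arm. The 23 libraries carried 18 tissue numbers, 3 for each of the 6 groups, and each tissue number is written here as 1 liver. The description of the series counts 1 liver fewer than there are tissue numbers. Which numbers share an animal stayed unresolved, and a p over such a pair would be too small. Newborn LV libraries held 13754065 to 20545715 UMIs and newborn untransduced ones 6074282 to 9883270. Juvenile LV libraries held 15282798 to 48302638, juvenile untransduced ones 13065982 to 42102948, adult LV ones 21085299 to 27979376 and adult untransduced ones 20650040 to 38678950. The median per spot ranged from 5884 to 25250 UMIs. By Xist and the Y-linked Ddx3y, the 6 newborn and juvenile LV livers were male, the untransduced livers of each of these ages were 2 females and 1 male, and the 6 adult livers were female.

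The first question was how much vector RNA each age carried, and 1 of the 2 custom sequences of the reference, g2060-AC-PL1, was read as LV-derived because its UMIs marked the LV livers. It reached 92.9 ± 42.8 CPM without TMM in newborn LV livers (SD, n = 3, 4257 UMIs) against 0.524 ± 0.592 in untransduced ones (22 UMIs). Juvenile livers carried 95.8 ± 35.6 against 0.219 ± 0.0791 CPM, and adult livers 8.42 ± 2.14 against 0.101 ± 0.112. The log2 change of g2060-AC-PL1 was 7.21 ± 0.56 in newborns (SE, adjusted p = 5.5e-06), 8.81 ± 0.58 in juveniles (adjusted p = 4.6e-07) and 6.22 ± 0.64 in adults (adjusted p = 3.4e-04). Among LV livers, adults were lower than juveniles by -3.12 ± 0.38 (adjusted p = 2.8e-05) and than newborns by -2.87 ± 0.38 (adjusted p = 3.6e-06), while juveniles and newborns differed by 0.26 ± 0.35 (adjusted p = 0.546). Sex separates the adult LV livers from the younger ones as age does. With sex as a term, the g2060-AC-PL1 difference between adult and juvenile was -3.35 with an adjusted p of 0.0701, the highest over its alternatives, which started at 9.2e-08. Only the newborn and juvenile untransduced groups held both sexes, with 0 to 18 UMIs of the sequence per liver. The sex term rests on these livers and can not part sex from age in LV livers. At least 1 UMI of the sequence lay in 44.4% (95% Clopper-Pearson interval 41.7 to 47.1) to 72.2% (69.2 to 75.0) of the spots of newborn LV libraries. The share ran from 48.3% (46.1 to 50.4) to 69.7% (67.1 to 72.2) in juvenile and from 9.83% (8.18 to 11.7) to 18.7% (16.6 to 21.0) in adult LV libraries. In untransduced libraries it was at most 1.12% (0.559 to 1.99), and 0 UMIs in 2 of them allowed up to 0.359 and 0.145 CPM.

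**Figure D1:**
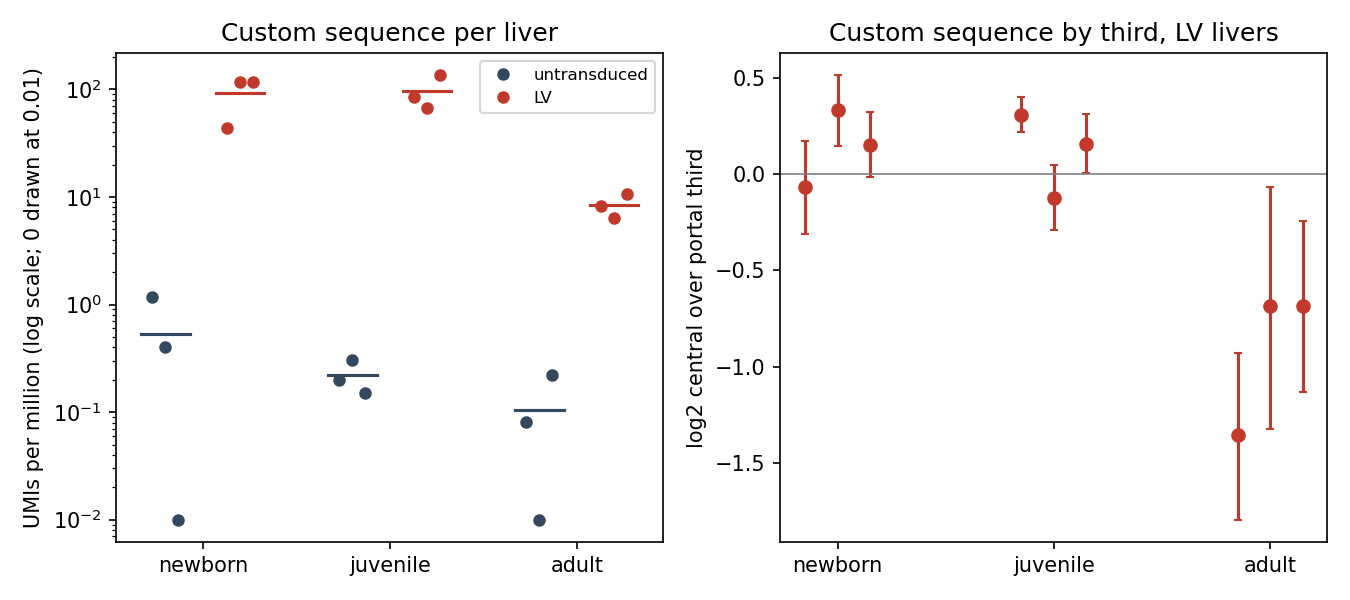
UMIs of the custom sequence g2060-AC-PL1 in CPM of each liver on a log axis, by age and arm, with 0 drawn at 0.01; and the log2 ratio of its level in the central over the portal group in each LV liver, with 95% intervals from the counts. The adult LV livers lie between 6.37 and 10.7 CPM and their ratios between -1.36 and -0.68.

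The next question was which liver genes differ 3 days after LV in newborns. Of 14573 genes tested, 91 were called, 13 higher and 78 lower, and 5 of the higher and 34 of the lower ones by at least 2-fold. The count was 16, 21, 27 and 39 without livers 1, 3, 5 and 4, 50 with sex as a term, 34 with the UMIs per spot as a term and 436 in a fit of the newborn livers alone. Outside the vector, the largest rise with at least 20 CPM was in Apol11b, an apolipoprotein L gene (ENSMUSG00000091694), by a log2 change of 2.24 ± 0.27 to 42.1 ± 5.61 CPM from 8.99 ± 1.70 (n = 3, adjusted p = 7.3e-04). The class I antigen-presentation gene H2-D1 (ENSMUSG00000073411) rose by 0.66 ± 0.12, and the liver X receptor gene Nr1h3 by 0.43 ± 0.07. Clec4f, the C-type lectin of Kupffer cells, the resident liver macrophages (ENSMUSG00000014542), fell by 2.05 ± 0.22 to 26.7 ± 3.90 CPM from 110.1 ± 8.27 (adjusted p = 2.1e-04). The macrophage receptor Vsig4 (ENSMUSG00000044206) fell by 1.82 ± 0.21 to 12.03 ± 1.88 from 42.4 ± 4.10 CPM, and the ion channel kinase gene Trpm7 fell by 1.47 ± 0.20. Parp14, which acts in the interferon response, fell by 1.37 ± 0.17, and Insig2, Pnisr, Aass, Igfbp3 and Vmp1 fell by 1.00 to 1.23. All 17 alternatives kept the calls of Apol11b, Clec4f, Vsig4, Trpm7 and Parp14. Vmp1 lost its call in 4 of them, Insig2 in 5, H2-D1, Nr1h3 and Aass in 6 each, and Pnisr and Igfbp3 in 7 each (adjusted p up to 0.252). With the UMIs per spot as a term, Insig2, Vmp1 and Pnisr fell by 0.74, 0.59 and 0.52. Between livers, 3111 genes did not overlap, 21.3% of those tested, where chance gives 10%.

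By list, of 14 Kupffer cell genes, 4 were lower, 0 higher and 10 not called, with 4 lower when adjusted over the list alone: Cd163 (-1.94 ± 0.26) and Folr2 (-1.02 ± 0.18) beside Clec4f and Vsig4 (list adjusted p = 1.2e-08; adjusted p = 0.25 with an estimated correlation). The 10 others had a median of 0.05. Of 17 alternatives, all kept the call of Cd163 and 6 ended that of Folr2 (adjusted p up to 0.120). Of 32 interferon-stimulated genes, 4 were lower and 28 not called, with 9 lower when adjusted over the list alone (adjusted p = 1.3e-16; adjusted p = 0.25 with an estimated correlation), among them Ifit3b at -1.48 ± 0.32 and Rtp4 at -0.94 ± 0.17. In the interferon-gamma list of 19 genes, Tgtp1 was lower (-1.56 ± 0.34). Of 12 class I presentation genes, H2-D1 was called and 6 were higher when adjusted over the list alone (adjusted p = 1.1e-04; adjusted p = 0.25 with an estimated correlation), and of 22 p53 targets Phlda3 rose by 1.04 ± 0.22. Rtp4, Phlda3, Ifit3b and Tgtp1 lost their calls in 5, 8, 9 and 9 of 17 alternatives (adjusted p up to 0.260). Ribosomal protein genes shifted by a median of 0.25 with 0 of 77 called in edgeR (adjusted p = 3.2e-08; adjusted p = 0.95 with an estimated correlation). No list kept its call with an estimated correlation, against 11 of 41 with the preset one.

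The same question in juveniles gave 29 genes, 17 higher and 12 lower, of which 17 and 11 changed at least 2-fold. Another split of the same livers, 7, 8 and 9 against 10, 11 and 12, called 1933 genes, and the first principal component, which parts these livers, held 47.9% of their variance. The scavenger receptor gene Marco (ENSMUSG00000026390) rose by 1.49 ± 0.27 to 88.0 ± 34.7 CPM from 31.1 ± 8.66 (n = 3, adjusted p = 0.0259), a call lost in 5 of 18 alternatives (adjusted p up to 1.00). Clec4f fell by 1.60 ± 0.21 to 45.3 ± 16.8 CPM from 136.7 ± 5.49 (adjusted p = 0.00438), and Vsig4 by 1.38 ± 0.21 to 18.01 ± 4.75 from 46.1 ± 13.8 (adjusted p = 0.00653). Both lost their calls with sex as a term (adjusted p = 0.0533 and 0.132) and in a fit of the juvenile livers alone (adjusted p = 0.724 and 0.786, the highest over their alternatives, which started at 8.2e-10 and 6.1e-07). The fetal gene Afp was lower in the mean, 7.70 ± 3.56 against 61.8 ± 53.5 CPM, and was not called (adjusted p = 0.117). Its change ran from -3.56 to -1.69 over 18 alternatives, of which DESeq2 (adjusted p = 2.3e-06), no filter and the fit without liver 8 called Afp. Non-overlapping genes numbered 1004, 6.89% of those tested against the 10% of chance. With sex as a term 2 genes were called, in a fit of the juvenile livers alone 1, and without livers 7, 9, 12, 8 and 10 the count was 17, 17, 19, 56 and 86.

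In the lists of the juvenile comparison, 5 of 14 Kupffer cell genes were lower, 1 was higher and 8 were not called, with Cd163 at -1.53 ± 0.23, Timd4 at -1.09 ± 0.20 and Folr2 at -0.99 ± 0.17 (adjusted p = 2.3e-09; adjusted p = 0.15 with an estimated correlation). The acute-phase gene Orm2 rose by 2.80 ± 0.34 to 28.1 from 4.25 CPM, 1 of 25 called in its list and 5 higher when adjusted over the list alone. T and NK cell genes, with Gzma at 1.63 ± 0.31, had 1 of 15 called and 10 higher when adjusted over the list alone, and monocyte genes, with Ccr2 at 1.86 ± 0.33, had 1 of 7 called and 4 higher. The T and NK cell list kept its call with an estimated correlation (adjusted p = 0.027), as did the cholangiocyte list, whose 10 genes had a median of -0.47 and 0 calls in edgeR (1 lower when adjusted over the list alone). Megakaryocyte genes had 0 of 9 called in edgeR and 7 higher when adjusted over the list alone. Igf2, of the fetal list, fell by 2.75 ± 0.40 to 1.58 from 12.03 CPM. Of 18 alternatives, 2 ended the call of Cd163, Orm2 and Igf2, 4 that of Folr2, 5 that of Timd4 and 6 that of Gzma and Ccr2, with adjusted p up to 0.711 for Cd163, 0.724 for Folr2, 0.109 for Orm2 and 1.00 for the others.

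**Figure D2:**
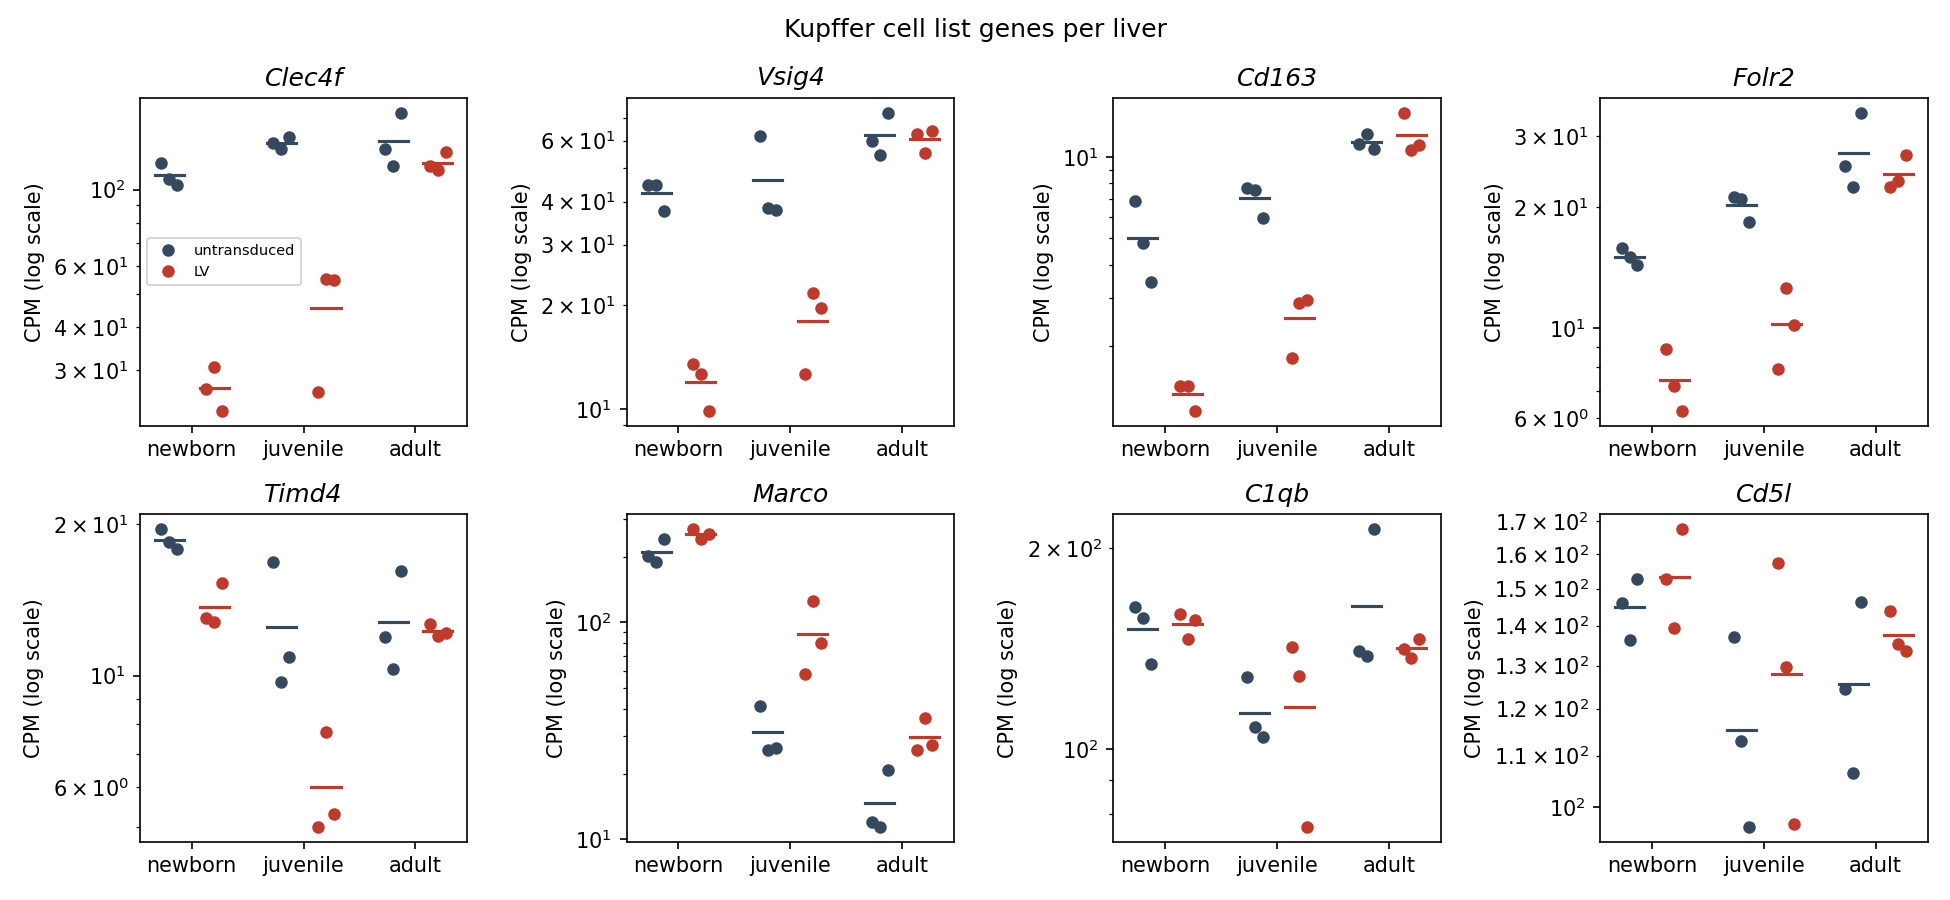
Expression of Kupffer cell genes in CPM on a log axis in LV and untransduced livers of each age, with a dot per liver and a bar at the mean of 3 livers. Clec4f lies at 26.7 against 110.1 CPM in newborn, 45.3 against 136.7 in juvenile and 119.8 against 138.3 in adult livers.

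In adults, the LV comparison called 20 genes, 11 higher and 9 lower. Alas1, the first enzyme of heme synthesis (ENSMUSG00000032786), rose by 2.35 ± 0.36 to 308.6 ± 91.3 CPM from 60.04 ± 31.7 (n = 3, adjusted p = 0.0238). The cytokine-induced gene Cish (ENSMUSG00000032578) rose by 1.499 ± 0.22 to 83.2 ± 3.40 from 29.6 ± 9.42 CPM, and Arid5b and the stress gene Ddit3 rose by 1.06 ± 0.20 and 1.01 ± 0.18. Bbc3 fell by 0.95 ± 0.17, Ggnbp1 by 0.78 ± 0.13 and Cmc2 by 0.54 ± 0.10. Each of these 7 genes lost its call in 4 to 7 of 17 alternatives (adjusted p up to 0.236). Leaving out liver 16 raised the count of called genes to 426 and leaving out livers 13, 15, 17, 18 and 14 lowered it to 1, 2, 3, 6 and 7, and with sex as a term it was 8; the share of called genes that were higher was 55.0% with TMM and 41.2% with RLE size factors. Non-overlapping genes numbered 2996, or 20.6% against the 10% of chance.

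Few list members were called in the adult LV comparison. Of 32 interferon-stimulated genes, 1 was lower and 31 were not called, with 6 lower when adjusted over the list alone (adjusted p = 1.4e-05; adjusted p = 1.00 with an estimated correlation). Cell cycle genes had a median of -1.21, 0 of 33 called in edgeR and 7 lower when adjusted over the list alone (adjusted p = 6.2e-09; adjusted p = 1.00 with an estimated correlation). None of the 14 Kupffer cell genes was called in edgeR, and 2 were higher when adjusted over the list alone (adjusted p = 0.57). Ddit3 was the 1 called gene of 18 in the endoplasmic reticulum stress list and Bbc3 that of 22 p53 targets.

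**Figure D3:**
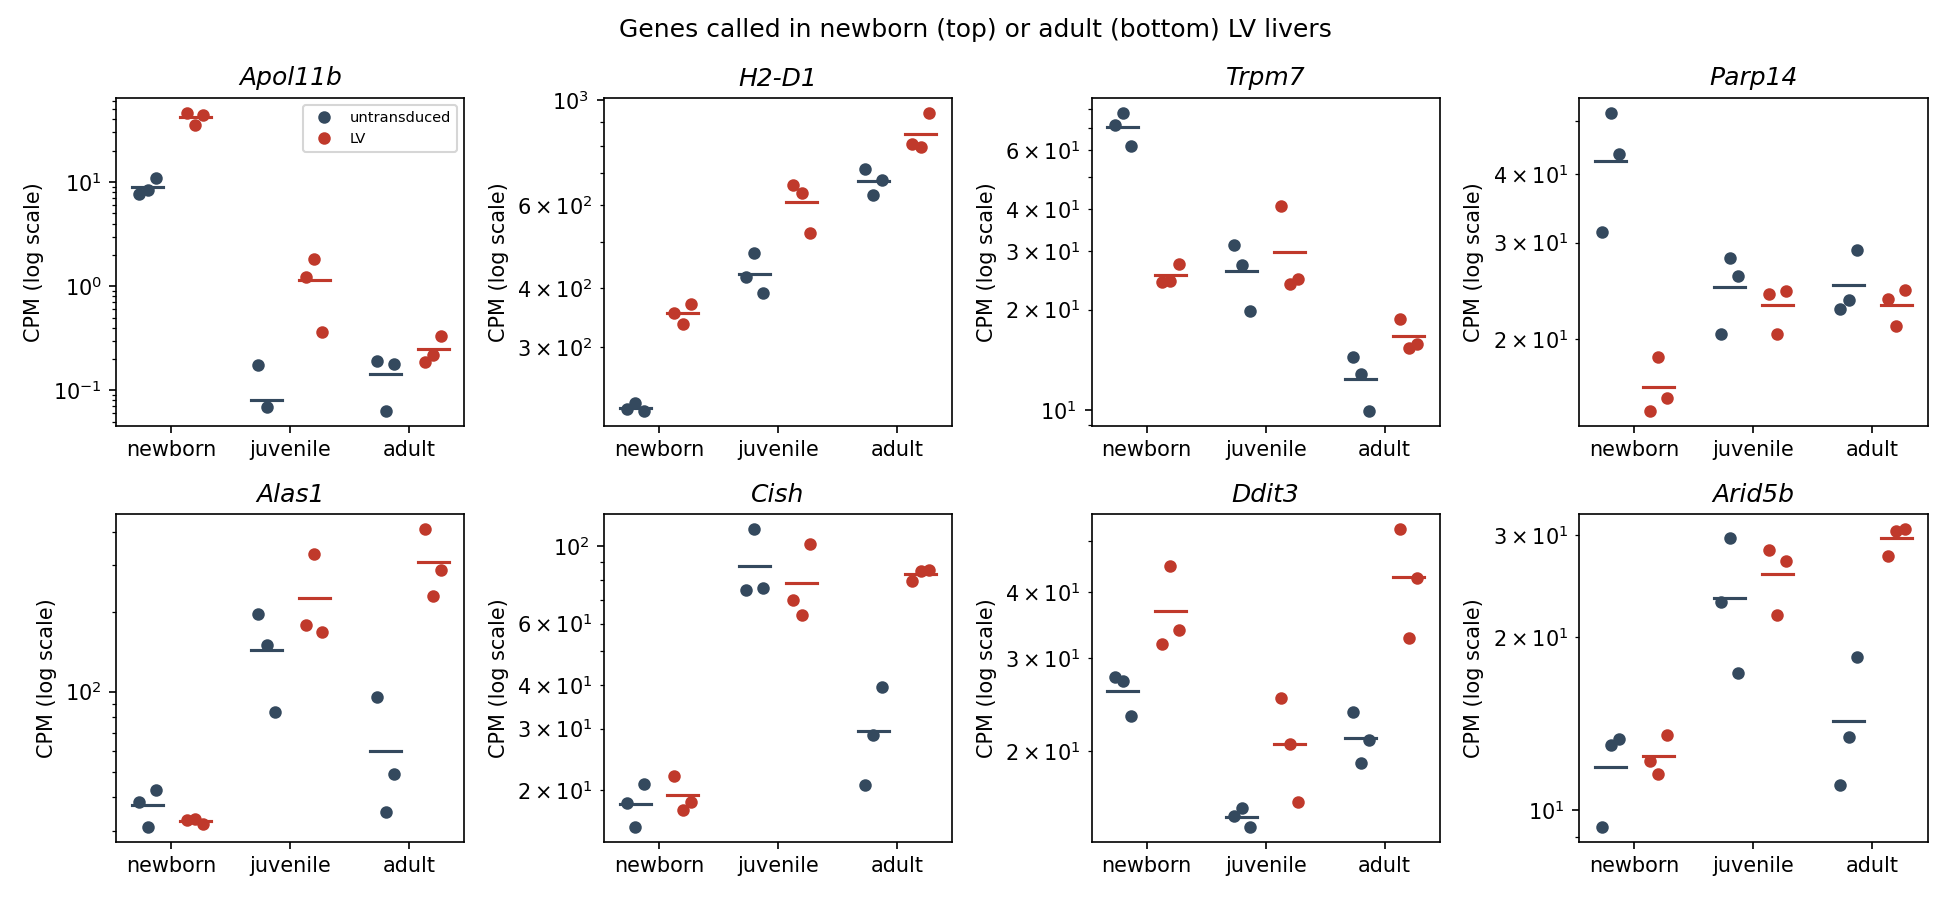
Expression of 8 genes in CPM on a log axis in LV and untransduced livers of each age, with a dot per liver and a bar at the mean of 3 livers; values of 0 are not drawn, which concerns juvenile untransduced Apol11b. Alas1 lies at 308.6 CPM in adult LV and 60.04 in adult untransduced livers, and Trpm7 at 25.3 in newborn LV and 70.3 in newborn untransduced livers.

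Whether the LV effect itself differed between ages was tested as an interaction, which called 10 genes. Clec4f changed by -2.05, -1.60 and -0.21 in newborn, juvenile and adult livers (adjusted p = 0.0471), Vsig4 by -1.82, -1.38 and -0.03 (adjusted p = 0.0471) and Cd163 by -1.94, -1.53 and 0.09 (adjusted p = 0.0471). Trpm7 changed by -1.47 in newborns, 0.20 in juveniles and 0.42 in adults (adjusted p = 0.0467). Cd209f, Phtf2, Bcl7a, Gtf2a2, Zrsr1 and Gfra1, chosen after their values were seen, were lower in newborn LV livers by -3.28, -1.17, -0.85, -0.89, -0.70 and -0.97. Cd209f was also called lower in juvenile LV livers (-1.38 ± 0.26, adjusted p = 0.0392), and the other 5 were not called there. Between pairs of ages, 23 genes differed in the LV effect between adult and newborn, with Clec4f at 1.84 ± 0.30 (adjusted p = 0.0221), and edgeR called 0 for juvenile against newborn and 0 for adult against juvenile. The custom sequence was not called in the interaction (adjusted p = 0.582). The count moved from 10 to 3 with RLE size factors, 2 with the UMIs per spot as a term, 5 with sex as a term and 177 with DESeq2. It was 0 in edgeR without any 1 of livers 1, 3, 5, 13, 14 or 17, and 42 without liver 16. Of 100 splits of the livers, the real one included, 19 gave at least 10 genes. Adult livers were all female and younger LV livers all male. Adult LV livers also carried less of the custom sequence, 8.42 CPM against 92.9 in newborn and 95.8 in juvenile ones. Age is thus not parted from sex or from the level of the sequence in the interaction.

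Postnatal change was read in the untransduced livers, and from newborn to juvenile 8457 genes were called, 4261 higher and 4196 lower. Hamp2, a hepcidin gene (ENSMUSG00000056978), rose by 5.93 ± 0.62 to 1984 ± 818.6 from 32.4 ± 14.7 CPM (n = 3, adjusted p = 6.2e-07), and the drug-metabolising gene Cyp2c29 rose by 5.72 ± 0.39. Thrsp and Scd1, which act in lipid synthesis, rose by 4.94 ± 1.04 and 4.51 ± 1.04, and Slco1a4, a bile salt and drug carrier, by 5.08 ± 0.35. Afp, the fetal counterpart of albumin, fell by 8.26 ± 0.83 to 61.8 ± 53.5 CPM (adjusted p = 3.5e-07), and the red cell antigen genes Kel and Rhd fell by 8.39 ± 0.46 and 8.38 ± 0.35. Cstdc4 and Stfa2l1, stefin-type protease inhibitors, fell by 8.64 ± 0.47 and 8.44 ± 0.41. The LV livers of these ages called 8234 genes, with 3533 higher and 3508 lower in both arms where chance gives 1195 and 1194, and 5 in opposite directions.

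By list, all 22 erythroid genes were lower in juvenile than newborn livers, Hbb-bs by -3.61 ± 0.41, and 22 were lower when adjusted over the list alone (adjusted p = 0.012 with an estimated correlation). All 16 fetal genes were lower, Igf2 by -7.58 ± 0.46 and Dlk1 by -7.79 ± 0.43 (adjusted p = 0.0061 with an estimated correlation). Of 18 bile acid genes 15 were higher, 1 lower and 2 not called, with Cyp27a1 at 3.19 ± 0.23 and Baat at 3.14 ± 0.16 (adjusted p = 0.021 with an estimated correlation). Of 31 P450 genes 25 were higher, 2 lower and 4 not called (adjusted p = 0.021 with an estimated correlation), and of 8 urea cycle genes 7 were higher and 1 not called, with Arg1 at 3.04 ± 0.20 (adjusted p = 0.11 with an estimated correlation). Neutrophil lineage genes were lower in 15 of 15, Mpo by -6.59 ± 0.50, and cell cycle genes in 32 of 33, and both lists lost their call with an estimated correlation (adjusted p = 0.11 and 0.43).

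From juvenile to adult, 5870 genes were called, 3013 higher and 2857 lower. The major urinary protein gene Mup17 (ENSMUSG00000096688) rose by 8.36 ± 1.44 to 756.8 ± 956 from 2.72 ± 2.23 CPM (n = 3, adjusted p = 3.4e-04), with a spread between adult livers larger than their mean. The sulfotransferase gene Sult3a1 rose by 7.67 ± 0.79 to 73.5 ± 26.8 from 0.576 ± 0.483 CPM, and Cyp2c38 by 6.85 ± 0.47. The lipase gene Lpl (ENSMUSG00000015568) fell by 4.66 ± 0.46 to 9.03 ± 0.121 from 228.3 ± 167.4 CPM, Sult2a1 by 3.66 ± 0.70, the collagen gene Col3a1 by 3.00 ± 0.36 and the replication gene Mcm6 by 2.46 ± 0.24. The 3 adult livers were female and 1 of the 3 juvenile livers was male. All 18 major urinary protein genes were higher (adjusted p = 0.39 with an estimated correlation), as were 58 of 77 ribosomal protein genes, Rpl10 by 1.28 ± 0.12 (adjusted p = 0.68 with an estimated correlation), and 27 of 31 proteasome genes (adjusted p = 0.31 with an estimated correlation). Cell cycle genes were lower in 31 of 33, Hells by -2.87 ± 0.38 (adjusted p = 0.33 with an estimated correlation). In LV livers 5017 genes were called, 2066 higher and 1770 lower in both arms where chance gives 527 and 484.

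From newborn to adult, 10725 genes were called, 5158 higher and 5567 lower. Mup1 rose by 8.48 ± 1.36 (6.98 to 13.28 over its alternatives, the highest without newborn liver 4), Mup16 by 7.66 ± 1.11 and Hamp2 by 7.005 ± 0.66 to 4174 ± 1229 CPM (n = 3, adjusted p = 5.6e-08). Igf2 (ENSMUSG00000048583) fell by 7.95 ± 0.47 to 9.44 ± 1.40 from 2329 ± 299.7 CPM, Kel by 8.07 ± 0.45 and the glypican gene Gpc3 by 7.92 ± 0.47. All 22 erythroid and all 16 fetal genes were lower (adjusted p = 0.035 and 0.02 with an estimated correlation), while 16 of 18 bile acid genes and 27 of 31 P450 genes were higher (adjusted p = 0.021 and 0.02). In LV livers 10416 genes were called, 4479 higher and 4738 lower in both arms.

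Zonation, the ordering of hepatocyte genes between portal tract and central vein, was compared between the central and portal groups of spots, with 6 livers per age. In newborns 439 genes were called, 242 higher centrally and 197 portally. The count was 256, 275, 279 and 291 without livers 4, 2, 1 and 5, and 106 in untransduced livers only. The ribonuclease genes Ang (ENSMUSG00000072115) and Rnase4 were higher centrally by 0.97 ± 0.06 and 0.96 ± 0.05 in 6 of 6 livers, with Ang at 149.7 against 76.7 CPM (adjusted p = 5.1e-15). Cyp2c37 followed at 0.78 ± 0.09. Spp1, the osteopontin gene (ENSMUSG00000029304), was higher portally at -1.51 ± 0.12, with 28.0 against 79.4 CPM, and Aldh1b1, Spink1 and Gls2 at -0.91 ± 0.06, -0.85 ± 0.07 and -0.68 ± 0.05. Thinned to 1000 UMIs per spot, 6 genes were called. Rnase4, Spp1 and Spink1 kept their calls at 0.40, -0.80 and -0.52, while Ang, Cyp2c37, Aldh1b1 and Gls2 lost theirs at 0.29, 0.29, -0.34 and -0.12 (adjusted p = 0.741, 0.926, 0.230 and 0.991). Of 22 central genes held out of the score 15 were higher centrally and 7 not called, Rhbg at 1.14 ± 0.12, and of 18 held-out portal genes 10 were lower, 1 higher and 7 not called (adjusted p = 0.0019 and 0.028 with an estimated correlation). Of 22 erythroid genes 9 were higher portally, with 20 when adjusted over the list alone (adjusted p = 0.0073 with an estimated correlation). Of 16 sinusoidal endothelial genes 5 were higher centrally, Lyve1 at 0.55 ± 0.08, with 12 when adjusted over the list alone (adjusted p = 0.013 with an estimated correlation). Rhbg and Lyve1 also lost their calls when thinned, at 0.18 and 0.30 (adjusted p = 0.991 for both).

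In juveniles 3049 genes were called between groups, 1420 higher centrally and 1629 portally. The count was 1965 and 1985 without livers 7 and 8, and 1864 in untransduced livers only. The phosphatase gene Lhpp (ENSMUSG00000030946) was higher centrally at 2.81 ± 0.08 in 6 of 6 livers, with 81.3 ± 15.1 against 13.2 ± 3.93 CPM (adjusted p = 2.0e-27), and Cyp2a5, Gstm2 and Gstm3 at 2.66 ± 0.08, 2.04 ± 0.05 and 1.98 ± 0.06. Spp1, Aldh1b1 and Etnppl were higher portally at -3.09 ± 0.11, -2.44 ± 0.06 and -2.15 ± 0.08. Thinning to 1000 UMIs left 424 calls. Held-out central genes were higher centrally in 22 of 22 and held-out portal genes portally in 17 of 18 (adjusted p = 0.0022 for each with an estimated correlation). Urea cycle genes were higher portally in 6 of 8, Arg1 at -0.86 ± 0.04, fatty acid oxidation genes centrally in 18 of 22, Cyp4a10 at 1.39 ± 0.08, and gluconeogenesis genes portally in 7 of 8, Tat at -0.80 ± 0.03 (adjusted p = 0.0041, 0.0026 and 0.011 with an estimated correlation). Acute-phase genes were higher portally in 20 of 25, Orm1 at -1.02 ± 0.06, 1 was higher centrally and 4 were not called (adjusted p = 0.038 with an estimated correlation). Kupffer cell genes were higher portally in 13 of 14, Marco at -0.82 ± 0.07 (adjusted p = 0.15 with an estimated correlation).

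In adults 3707 genes were called, 1802 higher centrally and 1905 portally. The ammonium transporter gene Rhbg (ENSMUSG00000104445) was higher centrally at 2.93 ± 0.09, with 49.6 ± 11.6 against 6.36 ± 0.735 CPM in 6 of 6 livers (adjusted p = 3.9e-26), Lhpp at 2.93 ± 0.06 and Slc13a3 at 2.84 ± 0.08. Spp1 was higher portally at -3.61 ± 0.11, Aldh1b1 at -3.13 ± 0.07, the cadherin gene Cdh1 at -2.91 ± 0.10 and Hsd17b6 at -2.80 ± 0.06. Thinning to 1000 UMIs left 592 calls. Male-biased liver genes were higher centrally in 10 of 12, portally in 2 and Cyp4a12a at 3.58 ± 0.43, in these female livers (adjusted p = 6.1e-04 with an estimated correlation). Proteasome genes were higher centrally in 30 of 31, Psmd1 at 0.51 ± 0.05, immediate early genes portally in 10 of 18 and centrally in 2, Nr4a1 at -1.29 ± 0.19, and Kupffer cell genes portally in 13 of 14, Marco at -0.65 ± 0.10 (adjusted p = 0.012, 0.014 and 0.039 with an estimated correlation). Thinned, Psmd1 and Marco lost their calls at 0.22 and -0.78 (adjusted p = 0.682 and 0.0918).

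**Figure D4:**
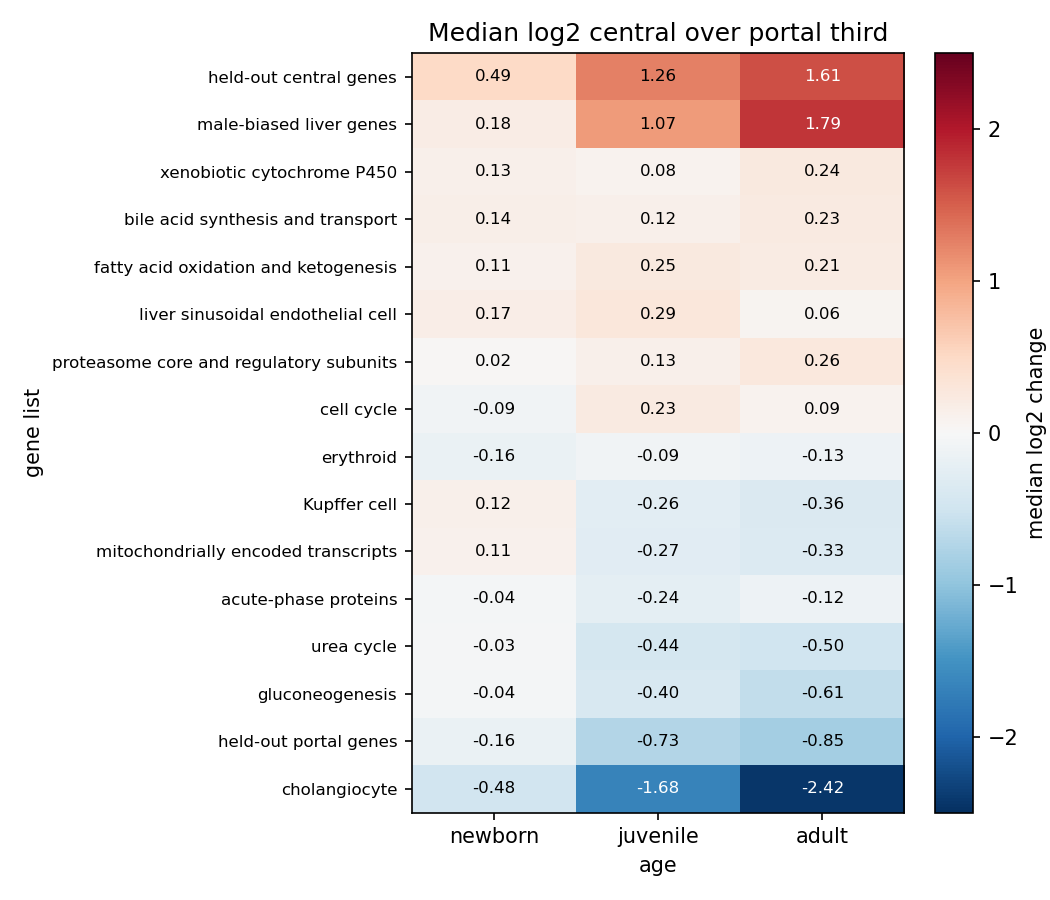
Median log2 change between the central and portal groups of the genes of each list, as a colour, by list and age, where positive values are higher in the central group. The values come from 6 livers per age.

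How zonation differed between ages was tested as an interaction of spot group and age, which called 1871 genes, 1636 of them with a larger absolute change in adult than in newborn livers. The sign of the change was opposite in newborn and adult livers for 918, and for 72 of the 248 that were called in newborns. Cyp2a5 went from 0.24 in newborn to 2.66 in juvenile and 2.69 in adult livers (adjusted p = 1.4e-08), and Cdh1 from -0.26 to -1.44 and -2.91 (adjusted p = 3.3e-18). Sult2a1 was higher centrally in newborns at 0.61 and portally in adults at -0.89 (adjusted p = 4.7e-13), with 0.09 in juveniles. Ang, at 0.97, 1.02 and 1.14, was not called (adjusted p = 0.159). Kupffer cell genes moved toward the portal group between newborn and juvenile livers in 13 of 14 and between newborn and adult livers in 12 of 14 (adjusted p = 0.0175 and 0.0063 with an estimated correlation). Urea cycle genes did so in 6 of 8 between newborn and juvenile livers, and male-biased genes moved toward the central group in 8 of 12 between juvenile and adult livers (adjusted p = 0.0017 and 2.1e-05 with an estimated correlation). Juvenile livers were of both sexes and adult ones female, so sex is not parted from age for the male-biased genes. Thinning to 1000 UMIs left 246 calls, and untransduced livers alone gave 871.

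As a single measure, the zonation strength of held-out genes was 0.669 ± 0.0748 in newborn, 2.07 ± 0.363 in juvenile and 2.73 ± 0.229 in adult livers (log2, SD, n = 6). Juvenile exceeded newborn livers by 1.40 (two-sided exact permutation p = 0.00216, adjusted 0.00325, the smallest p that 924 splits allow), adult exceeded juvenile livers by 0.66 (exact p = 0.00433) and newborn livers by 2.06 (exact p = 0.00216). All adult livers were female. Among juveniles, the female livers 8 and 12 had 2.53 and 2.32, and the male livers 7, 9, 10 and 11 had 2.30, 1.64, 1.78 and 1.83. Sex is thus not parted from age in the difference between adult and juvenile livers. Moran's I of the same genes over neighbouring spots was 0.180 ± 0.0620 in newborn, 0.426 ± 0.0968 in juvenile and 0.560 ± 0.0257 in adult livers, with differences of 0.247, 0.134 and 0.381 (exact p = 0.00433, 0.00216 and 0.00216). With a second ring of neighbours the juvenile minus newborn difference was 0.0718 (adjusted exact p = 0.145). Adult LV livers had a strength of 2.57 ± 0.216 against 2.89 ± 0.0760 in untransduced ones (exact p = 0.1, the smallest possible with 3 against 3), juvenile ones 1.91 against 2.23 (exact p = 0.2) and newborn ones 0.676 against 0.661 (exact p = 0.9). Moran's I was 0.235 ± 0.0183 in newborn LV livers against 0.125 ± 0.0141 in untransduced ones (exact p = 0.1, the smallest possible), 0.376 against 0.476 in juvenile ones (exact p = 0.2) and 0.541 against 0.579 in adult ones (exact p = 0.1). Newborn LV libraries held more UMIs than untransduced ones, and whether depth accounts for the newborn difference stayed unresolved: thinned to 1000 UMIs per spot, all 6 newborn livers fell to 0.0123 to 0.0563, close to 0. LV liver 2, at a median of 8594 UMIs per spot, had 0.216, and the A library of untransduced liver 4, at 8864, had 0.120.

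**Figure D5:**
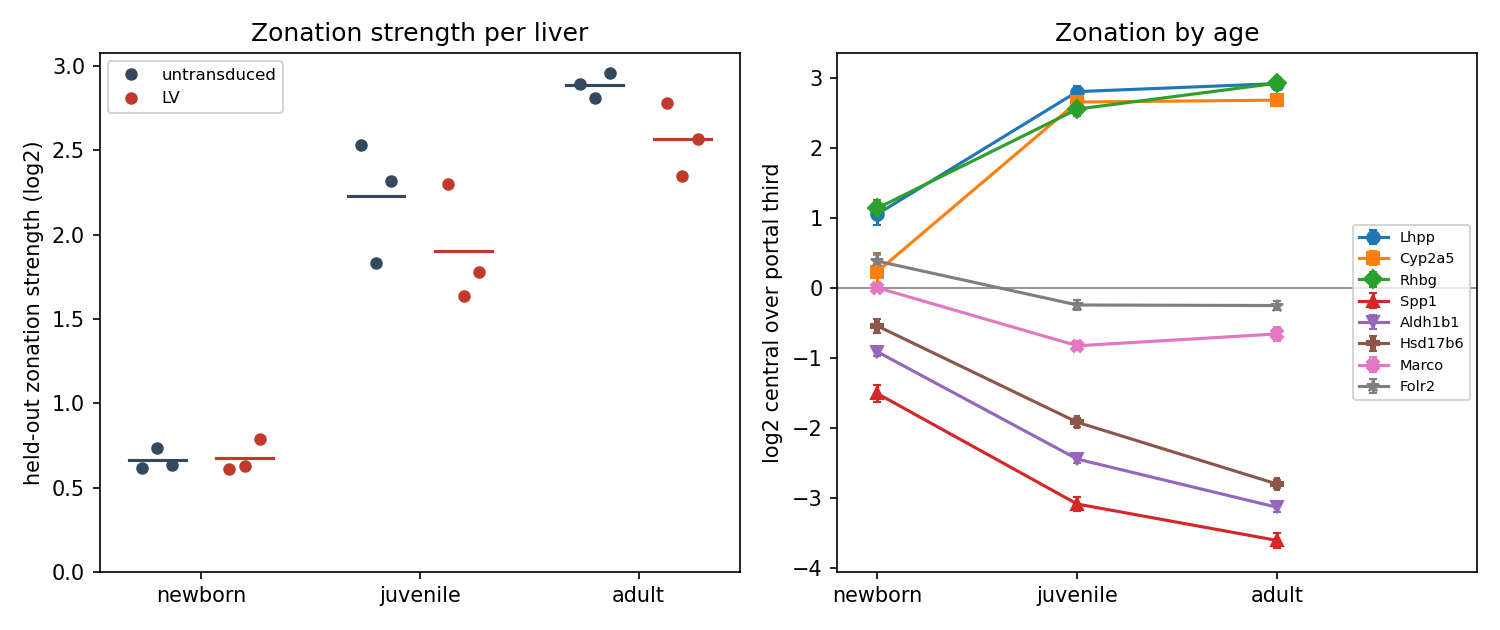
Zonation strength of held-out genes (log2) of each liver by age and arm, with a dot per liver, and the log2 change between central and portal groups of single genes by age, with bars of 1 SE. Strength has means of 0.669 in newborn, 2.07 in juvenile and 2.73 in adult livers.

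Whether LV altered zonation was tested as an interaction of spot group and LV within each age. In newborns edgeR and DESeq2 called 0 genes, with 539 at an unadjusted p under 0.05. In juveniles 13 genes were called, 8 of them with a change more toward the central group in LV livers: Nnmt and Gsn differed by 0.84 ± 0.14 and 0.75 ± 0.13 and Marco by 0.73 ± 0.13, while the neutrophil gene S100a9 differed by -0.84 ± 0.14 (adjusted p = 0.00147) and Cyp7a1 by -0.54 ± 0.10. Of 13 alternatives, 3 ended the calls of Nnmt and Gsn, 4 those of Marco and Cyp7a1 and 5 that of S100a9 (adjusted p up to 1.00), and thinned Cyp7a1 differed by -0.03. The count was 35 without liver 7 and 2 without liver 8. In adults 11 genes were called, 7 more central in LV livers, with Gsn at 0.74 ± 0.14, Serpina12 at 0.66 ± 0.10 (adjusted p = 2.3e-04) and Scd1 at 0.54 ± 0.11, and Cyp2c54 at -0.48 ± 0.10. Of 13 alternatives, 2 ended the call of Serpina12, 5 those of Gsn and Scd1 and 6 that of Cyp2c54 (adjusted p up to 1.00), and the count was 24 without liver 16. DESeq2 called 1 gene in juveniles and 4 in adults, thinning to 1000 UMIs left 0 and 1, and no filter gave 47 and 66. Male-biased genes had a median difference of -0.47 in adults, toward less central bias in LV livers, with 1 of 12 called and 5 when adjusted over the list alone (adjusted p = 0.0018 with an estimated correlation).

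Where the vector lay along the same axis was the next question. The log2 ratio of g2060-AC-PL1 between the central and the portal group was -1.36 (95% interval -1.80 to -0.93), -0.69 (-1.32 to -0.07) and -0.68 (-1.13 to -0.24) in the 3 adult LV livers, from 64 against 162, 36 against 60 and 68 against 120 UMIs. Newborn LV livers had -0.07, 0.33 and 0.16 and juvenile ones 0.31, -0.12 and 0.16. The adult mean of -0.91 ± 0.39 (n = 3) differed from that of the younger livers, 0.13 ± 0.19 (n = 6), by -1.04 (two-sided exact permutation p = 0.0238, the smallest possible with 84 splits). Against newborn and juvenile livers alone the exact p was 0.1, the smallest possible. Thinned to 1000 UMIs, 18 UMIs were left in the central and portal groups of adult livers and the adult mean was -0.33 ± 0.58 (exact p = 0.190).

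Spots with a UMI of the custom sequence were then compared with spots of the same library, group and depth without one. A partner was found for 512 of 573, 429 of 811 and 233 of 700 such spots in newborn livers 1, 2 and 3. In juveniles the A and B libraries of liver 7 had partners for 744 of 1178 and 740 of 1467. Livers 9 and 10 had them for 848 of 997 and 306 of 877. Nearly all were paired in adults (235 of 236 in liver 15). Newborn and juvenile results thus cover only a part of these spots. In newborns 15 of 12559 genes were called, 6 higher and 9 lower, led by the platelet gene Pf4 at -0.35 ± 0.06 and mt-Co1 at -0.18 ± 0.03, each of which was higher in 1 of 3 livers, with Apoa4 at 0.22 ± 0.04 in 3 of 3 livers. In juveniles 20 were called, 2 higher and 18 lower, and the neutrophil genes S100a9, Camp and Ltf fell by 0.67 ± 0.05, 0.86 ± 0.08 and 1.12 ± 0.17 in 3 of 3 livers. In adults 3 were called, the immunoglobulin gene Igkc at 1.05 ± 0.16, Hbb-bs at 0.32 ± 0.05, and Iglc1 at -2.98 ± 0.33 although 2 of 3 livers were higher. Mitochondrially encoded genes were lower in 6 of 13 in newborns (each of the 6 higher in 1 of 3 livers) and 5 of 13 in juveniles, and neutrophil genes in 5 of 15 in juveniles (adjusted p = 0.27, 0.27 and 0.0645 with an estimated correlation). These genes were chosen by smallest p, after their values were seen.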

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

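Of the tests in this part, those of fewer Kupffer cells, of sex, of depth between the arms and of UMIs per spot in the portal group were chosen after the result was seen, as were all tests of the custom sequences and those with sex or UMIs per spot as a term.

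Differences between ages or arms were found in several results. The LV effect differed between ages for 10 genes, with adjusted p of 0.0471 for Clec4f, 0.0471 for Vsig4, 0.0471 for Cd163 and 0.0467 for Trpm7. Of 100 splits of the livers, 19 gave at least as many genes, up to 1860 against the real 10, so chance can not be excluded for that count, and the splits with many genes point to a structure of the samples beside LV and age. In edgeR the count was 0 without any 1 of livers 1, 3, 5, 13, 14 or 17, 1 without 2 or 11, 2 without 4, 6 or 15, 4 without 18, 6 without 9 or 12, 18 without 7, 24 without 8 and 42 without 16. Zonation differed between ages for 1871 genes, and the other 59 of 60 splits reached at most 412 genes. Of 28 zonation genes followed under the alternatives, not all of them named here, 26 were among the 1871. They were picked by rule from these same livers, so that share is no independent support. Zonation differed with LV for 13 genes in juveniles and 11 in adults. In juveniles 5 of 10 splits gave as many genes, up to 97, and in adults the highest of the other splits was 7, with 10 splits too few for a share under 0.05. The juvenile count was 35 without liver 7 and 2 without liver 8, and the adult count was 24 without liver 16.

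The lower Clec4f, Vsig4, Cd163 and Folr2 of newborn and juvenile LV livers, with means of -1.71 ± 0.22 and -1.37 ± 0.20 (mean SE), were weighed against 3 explanations. A loss of Kupffer cells would lower the other 10 tested Kupffer cell genes by about as much, but their median was 0.0507 in newborns (SD 0.219, -0.45 for Timd4 to 0.27) and 0.0680 in juveniles (SD 0.645, -1.09 for Timd4, which was called, to 1.49 for Marco). The 4 genes were set apart by their calls in these livers, so in newborns the other 10 are those not called. Their median is thus no independent test, and it shows only that the fall was not shared by the whole list. With sex as a term the means were -1.68 ± 0.26 and -1.35 ± 0.25, and the larger SE left 3 and 0 of the 4 genes called. The term rests on the newborn and juvenile untransduced livers, the only groups with both sexes. It takes the sex difference as equal at all ages and in both arms. A sex difference of that kind did not account for the fold, but one that differs by age or arm can not be parted from LV. With the log2 of UMIs per spot as a term the means were -1.60 ± 0.27 and -1.37 ± 0.20, with 3 and 4 of the 4 genes called. A trend with depth fitted over all livers thus did not account for the fold. In newborns the median UMIs per spot nearly part the arms, at 8594 to 14880 in LV and 5884 to 8864 in untransduced libraries. A steeper trend in newborns is therefore not excluded. What stays open is a loss of some of the cells, a replacement by other macrophages or a change in their state, which may be biological and is a hypothesis found and tested on the same livers, in a design where younger LV livers are male and adult livers female.

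The lower level of the custom sequence in the central than in the portal group of adult LV livers, which differed from the younger livers by -1.04, was weighed next. The median UMIs per spot differed between the central and portal groups by at most -0.0516, -0.0217 and -0.106 (log2) in livers 13, 14 and 15, less than the UMIs of the sequence, at -1.34, -0.74 and -0.82 (upper 95% ends -0.91, -0.12 and -0.38), so more UMIs per spot on the portal side was not the whole of it. These ends cover counting error only. Over the spots of adult LV libraries the sequence varied 1.33 to 1.66 times as much as counting error gives, so they are too narrow, and liver 14 came nearest to its depth ratio. The other divisions of spots left the ratio of the sequence below 0 in each adult liver, except after thinning. With the central-side score, liver 14 had -0.52 with a 95% interval of -1.15 to 0.096, which includes 0. After thinning, 18 UMIs in the 2 groups gave a highest ratio of 0, too few to tell the division and the biology apart. Spots with a UMI of the sequence were not called higher for Kupffer, endothelial or cholangiocyte genes in adults (smallest adjusted p = 0.225), but a p that misses the threshold sets no bound on their share, so the outcome written beforehand as evidence against them was wrong and vector RNA in portal-side cells other than hepatocytes stays open. A difference between adult and younger hepatocytes in where the vector enters or is expressed may be part of it and was not tested apart from sex.

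The weaker zonation of newborn livers was weighed against their lower depth. Zonation strength differed by 1.40 between juvenile and newborn, 0.66 between adult and juvenile and 2.06 between adult and newborn livers, and Moran's I by 0.247, 0.134 and 0.381. With every spot thinned to 1000 UMIs the adult minus newborn difference was 2.12 (exact permutation p = 0.00216, 6 livers against 6), so equal UMIs per spot did not remove it. Thinned newborn libraries kept 3 to 5 of the 7 central and 4 to 5 of the 7 portal score genes, against 6 to 7 and 7 in adults, and newborn strength fell to 0.149, so lower expression of the score genes in newborns, and the size of the lobule against that of a spot, stay open. All adult livers were female while the newborn and juvenile ones were of both sexes, so sex is not parted from age. A biological difference with age is a hypothesis that these data may fit.

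A value far from the others of its group was found in 1 of 67 groups of livers or libraries. Newborn liver 3 had a log2 central over portal ratio of Rhbg of 1.38, against 0.98 to 1.06 in the other newborn livers. Chance alone gives 1 in 20 of the groups tested. The groups for spots, UMIs and mitochondrial share were of libraries, and those of the newborn LV arm were counted but too small to be tested. The second custom sequence, gLVIFNA, had 26 UMIs in 26 spots of 1 juvenile LV library of liver 7, 1 UMI in newborn LV liver 1 and 0 in every other library, untransduced ones included.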

How the results depend on the processing

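Chosen after the results were seen were the alternatives with sex, UMIs per spot or the juvenile principal component as a term, 1 library per tissue number, LV livers only, and those of the custom sequence. The cause of the changes was not tested, except that fewer livers or UMIs entered where a liver, a group or UMIs were left out.

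The counts of genes that differ with age kept within 1.5 times their value under all alternatives run. The counts of LV genes did not. In newborns the 91 genes became 172 with DESeq2, 194 with libraries not added, 216 with the replicate block and libraries not added, 50 with sex as a term and 436 in a fit of the 2 groups only. In juveniles the 29 became 54, 84, 81, 2 and 1 in the same order, and 47 with the juvenile principal component. In adults the 20 became 303, 404 and 468, then 51 with 1 library per tissue number and 3 with the 2 groups only. With sex as a term the adult count was 8, although all adults were female. With UMIs per spot as a term the counts were 34, 32 and 25, and 2 for the interaction. The 10 genes of the interaction became 177 with DESeq2, 3 with RLE size factors, 20 with no filter, 146 with libraries not added, 185 with the block and libraries not added, 5 with sex as a term, 1 with 1 library per tissue number and 55 with the principal component.

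Thinning spots to 1000 UMIs left 6 of the 439 newborn, 424 of the 3049 juvenile and 592 of the 3707 adult zonation genes, counted without asking which, and 246 of those that differ between ages. Thinning removed most UMIs and also redrew the score and the groups of spots, and these counts do not part the 2. Untransduced livers only gave 106, 1864 and 871 for newborn, juvenile and the difference between ages. For zonation with LV, DESeq2 called 1 gene in juveniles and 4 in adults, no filter 47 and 66, and thinning 0 and 1 in edgeR; the central-side score called 19 in adults. In newborns edgeR and DESeq2 called 0 genes, as under each alternative, with 539 at an unadjusted p under 0.05.

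Left out 1 at a time, the livers gave 16 to 77 LV genes in newborns, with 16 without liver 1, 21 without 3, 27 without 5 and 39 without 4. In juveniles the range was 17 to 86, with 17 without 7, 17 without 9, 19 without 12, 56 without 8 and 86 without 10. In adults it was 1 to 426, with 1 without 13, 2 without 15, 3 without 17, 6 without 18, 7 without 14 and 426 without 16. The interaction ranged from 0 to 42. Zonation genes ranged from 256 to 321 in newborns (256 without 4, 275 without 2, 279 without 1, 291 without 5) and from 1965 to 2981 in juveniles (1965 without 7, 1985 without 8). Zonation with LV ranged from 2 to 35 in juveniles (2 without 8, 35 without 7) and from 8 to 24 in adults (24 without 16).

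Counts between ages ranged from 7538 to 8220 for juvenile against newborn, 4737 to 5474 for adult against juvenile and 10107 to 10427 for adult against newborn, those of adult zonation from 2903 to 3494 and those of zonation between ages from 1574 to 1887. Zonation strength differed by 1.305 to 1.484, 0.57 to 0.75 and 2.01 to 2.13 (juvenile minus newborn, adult minus juvenile, adult minus newborn) and Moran's I by 0.230 to 0.282, 0.0989 to 0.151 and 0.367 to 0.395, all with exact permutation p under 0.05.

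The custom sequence kept its calls against untransduced livers under all alternatives. Between adult and juvenile LV livers it lost its call only with sex as a term (-3.35, adjusted p = 0.0701). That term rests on untransduced livers with few UMIs of the sequence and can not part sex from age in LV livers. Over all its alternatives the difference was -3.40 to -2.84, with adjusted p from 9.2e-08. Its adult ratio between central and portal spots was -0.33 when thinned (exact permutation p = 0.190).

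With 3 livers per age the exact p can not fall below 0.1. Zonation strength then differed by 1.57, 0.66 and 2.23 (juvenile minus newborn, adult minus juvenile, adult minus newborn) in untransduced and by 1.23, 0.66 and 1.89 in LV livers. Moran's I differed by 0.351, 0.103 and 0.455 in untransduced and by 0.142, 0.165 and 0.307 in LV livers (adjusted exact p = 0.2, 0.15 and 0.15), and by 0.0718 between juvenile and newborn livers with a second ring of neighbours (adjusted exact p = 0.145).

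With the correlation between genes estimated, the lists called fell from 11 to 0, 16 to 2 and 4 to 0 of 41 for LV in newborns, juveniles and adults, and from 20 to 5, 15 to 0 and 24 to 6 for juvenile against newborn, adult against juvenile and adult against newborn. Between groups of spots they fell from 18 to 7, 21 to 9 and 23 to 13 of 39 by age, and for zonation with LV from 7 to 0, 16 to 0 and 10 to 1. Under alternatives, 2028 values were read for 131 pairs of a gene and a comparison. Some genes entered in several comparisons, and some are not named here. Of these values, 1759 kept their direction and side of the threshold, 266 lost their call, 3 gained a call and 0 reversed.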

Other observations

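The tests of spots with a UMI of the custom sequence, of LV livers only and with the juvenile principal component were chosen after results were seen.

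For the LV comparisons and those between ages, 3 livers against 3 make 10 splits, too few for a share under 0.05. In newborns the real split called 91 genes and the highest other 0, and in adults 20 against 9. In juveniles the real split called 29 genes and 1 other, livers 7, 8 and 9 against 10, 11 and 12, called 1933, which points to a structure of the juvenile livers that is not LV: the first principal component held 47.9% of their variance and put livers 7, 8 and 9 at -1, -0.696 and -0.332 and livers 10, 11 and 12 at 0.800, 0.606 and 0.621. With this component as a term, 47 LV genes were called in juveniles. For juvenile against newborn, adult against juvenile and adult against newborn the real split was 1 of 10 and the highest other called 0 genes, against 8457, 5870 and 10725. For zonation, 1 of 32 splits reached the real count at each age, with the highest other at 93 in newborns (439), 1605 in juveniles (3049) and 1666 in adults (3707). The other splits swapped the central and portal groups in some livers, while the score had set these groups the same way in every liver. A lower count is thus built into the other splits, and they do not decide on chance. For zonation with LV in newborns, 10 of 10 splits called 0 genes.

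That spots with a UMI of the custom sequence hold more Kupffer or endothelial RNA was tested with the lists of both cell types in spots paired by library, group of spots and depth. Both lists went up in newborns and adults and down in juveniles, and the smaller adjusted p with an estimated correlation was 0.270 in newborns, 0.272 for the decrease in juveniles and 0.731 in adults. With the preset correlation the juvenile Kupffer list was called lower (median -0.0520, adjusted p = 0.0439, 3 of 14 lower and 0 higher when adjusted over the list alone), which goes against a rise there. A p that misses the threshold sets no bound on a rise, so the outcome written beforehand as evidence against one was wrong, and more RNA of these cells may be present in newborns and adults and is not excluded in juveniles.

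Moran's I of the custom sequence over neighbouring spots was 0.274 and 0.297 in the libraries of juvenile liver 7 and 0.0013 to 0.105 in the other LV libraries. The nuclear transcripts Malat1 and Neat1 were not called in any LV comparison, with log2 changes of 0.20, -0.49 and -0.16 for Malat1 and -0.06, 0.04 and 0.02 for Neat1 in newborns, juveniles and adults.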
